A study of Mus musculus with 7 samples.

How the data were processed

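Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on freshly dissected tissue of mouse embryos. Shox2 was precipitated with an antibody against HA, an epitope tag carried by the Shox2 protein of these animals, and Pbx with an antibody against Pbx proteins. The series holds 7 libraries, 1 per group. Peak lists of 3 of them were used: Shox2 in limb, Shox2 in palate and Pbx in limb, all at E12.5 (embryonic day). The other 4 libraries (Shox2 in limb at E13.5, Shox2 in a limb and palate mix, the anti-HA ChIP from untagged embryos and the input) were not analysed here, so no list of background regions was set against the results. A further list for the series gave the regions called co-occupied by Shox2 and Pbx.

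Per the labels' protocols, a commercial high-sensitivity ChIP kit was followed, and ChIP and input DNA were made into Illumina libraries by end polishing, adapter ligation and a final PCR. Per the submitters' processing notes, Bowtie and MACS2 were used with the mouse build mm9; versions, the peak calling settings and the rule by which the lists were ended are not given in the sources used here. The signal tracks, which were not used here, are described per the labels as filtered against the untagged ChIP; whether the same was done for the peak lists is not stated.

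The deposited lists hold only a chromosome, a start and an end for each peak, with no height, score, fold or p-value. The depth of the libraries is therefore unknown, and no value below carries a counting error from reads. Both limb lists have exactly 33915 peaks. Their widths fall from the top of the file to the bottom (Spearman's rho of width with line number -0.58 for Shox2 and -0.51 for Pbx, across peaks), so the file order was treated as a possible ranking, which the files do not state. The palate list has only positions of 1 bp, as a list of summits would. Sequence names and the highest positions were compared with a table of GRCm38 genes: on 10 of 20 chromosomes a peak lay beyond the last GRCm38 gene. A peak can lie beyond the last gene in its own build too, so this count cannot tell the builds apart. The build was taken from the processing notes, and the files were kept in mm9. No mm9 genome or annotation was used here, and coordinates were not converted. Peaks are therefore located by position alone, and planned tests of promoters, gene lists near peaks and sequence motifs were not run. Positions are given below as windows in Mb of mm9.

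Lists were compared by overlap of at least 1 bp. Since a palate peak is 1 bp wide, a palate peak overlaps another list when its position lies inside one of that list's peaks. Chance overlap was measured with 1000 circular shifts, in which the second list was moved along each chromosome by 1 random distance per chromosome within the span covered by peaks. This keeps peak widths and clustering. A second chance level came from 1000 local shifts of 5 to 20 kb to either side, which also keep the density of peaks in each neighbourhood. Permutation p-values were one-sided, and 0.001 is the smallest that 1000 shifts can give. Intervals of 95% were drawn from 1000 bootstraps of whole chromosomes. Shares within 2 classes of peaks were compared with two-sided Fisher's exact tests. Where peaks of different extent had to be compared, each was set to 200 bp around its centre. Place in the list and peak width were held fixed with Mantel-Haenszel odds ratios over deciles of each, with the Cochran-Mantel-Haenszel chi-square test. Where these odds ratios are given at 200 bp, only the overlap with Pbx was taken at that width. Shared peaks were defined at the deposited extents. Because neighbouring peaks are not independent and each group has 1 library, every p-value describes these lists and not the spread between embryos.

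For the comparison of limb and palate, peaks were counted in windows of 1 Mb, and windows with at least 5 Shox2 peaks in both lists together were tested with Fisher's exact test against all other peaks, with Benjamini-Hochberg adjustment over windows and a threshold of 0.05. Odds ratios had 0.5 added to each cell. The windows named were fixed by rule before the data were examined: the 10 with the most co-occupied peaks, and the 5 with the smallest p in each direction of the limb and palate test. The comparisons, tests and most alternatives were fixed at the same time. Alternatives were other definitions of overlap, the widest 50% of each limb list, thinning to 15091 peaks, autosomes only, other chance levels and other window rules. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

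The code was tested on simulated data. When one list was moved at random, the shift test passed the threshold in 2 of 20 runs for limb Shox2 on Pbx and in 0 of 20 for each of the palate comparisons. When 20% of Shox2 peaks were given a partner, the excess over chance came back as 21.5% for limb Shox2 on Pbx, 20.3% for palate Shox2 on Pbx and 20.0% for palate on limb Shox2. The window test gave 0 false calls when the limb list was split at random into a larger and a smaller part. With the peaks of the larger part reduced 4-fold in 20 windows, it called 2 of them, so it missed most reductions of that size. Both parts are smaller than the real lists and no palate peaks were used. The sensitivity of the limb and palate comparison itself was therefore not measured.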

Results

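The study profiled where Shox2 binds in the embryonic mouse limb and palate, and where Pbx binds in the limb. Shox2 is a homeodomain transcription factor needed for the proximal limb skeleton. Pbx proteins belong to the TALE class of homeodomain factors, which often bind DNA together with other homeodomain proteins. At E12.5 (days of embryonic development) the Shox2 limb list held 33915 peaks with a median width of 261 bp, covering 10.8 Mb. The Pbx limb list held 33915 peaks with a median width of 897 bp, covering 35.2 Mb. The Shox2 palate list held 15091 positions of 1 bp. Sequencing depth was unknown for all of them, and each group had 1 library, so no value below has a replicate error. In all lists, peaks were sparse on the X chromosome. Shox2 limb peaks lay at 4.38 per Mb on X, against 7.74 (chromosome 7) to 17.9 (chromosome 18) per Mb on the autosomes. Pbx peaks lay at 2.42 per Mb on X and at 11.6 to 18.3 per Mb on the autosomes. Palate Shox2 peaks lay at 0.796 per Mb on X and at 5.22 to 7.54 per Mb on the autosomes.

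**Figure D1:**
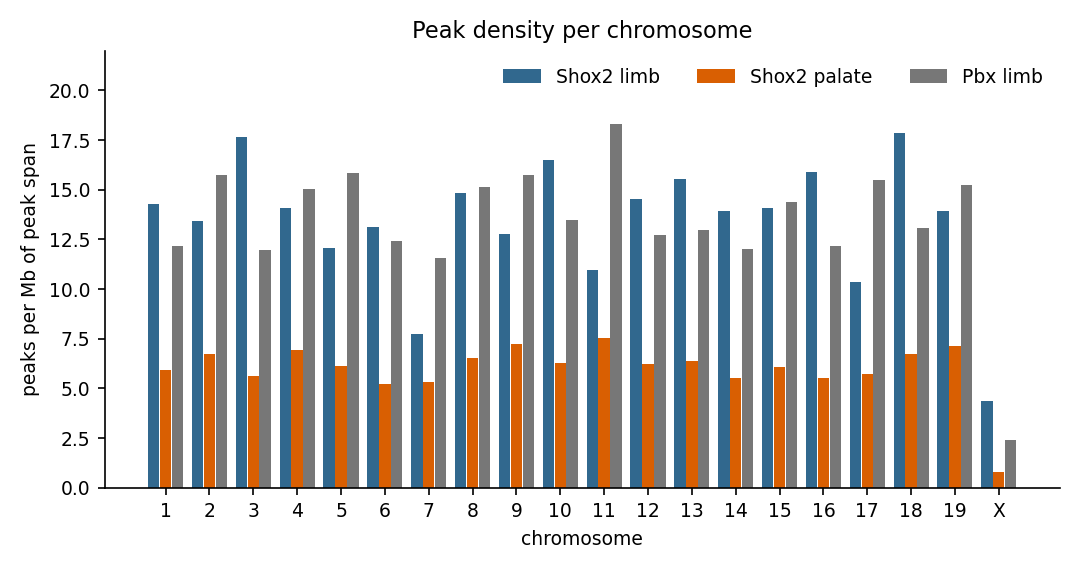
Peaks per Mb (linear axis, from 0) on each mouse chromosome for the Shox2 limb, Shox2 palate and Pbx limb lists, 1 library each, per Mb between the first and the last peak of a chromosome in mm9. All 3 lists are lowest on X, where palate Shox2 peaks reach 0.796 per Mb.

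The first comparison asked how far Shox2 and Pbx occupy the same sites in the limb. Of the Shox2 limb peaks, 8999 (26.5%, 95% chromosome bootstrap interval 25.8 to 27.4%) overlapped a Pbx limb peak. From the other side, 7927 Pbx peaks (23.4%) overlapped a Shox2 peak. Circular shifts of the Pbx list gave 1.83% ± 0.087 (SD over 1000 shifts), so the overlap was 14.5-fold above chance (permutation test, one-sided p = 0.001, the smallest the shifts can give). Shifts of 5 to 20 kb, which keep the neighbourhoods of both lists, gave 2.81%, and the overlap was 9.44-fold above that level (permutation p = 0.001). Neither kind of shift keeps the moved peaks on sites that ChIP can enrich, and no list of background regions was used. Here and below, the excess is therefore over shifted positions only. The other 73.5% of Shox2 limb peaks met no Pbx peak in the list. The overlap was seen on every chromosome, from 24.2% on chromosome 16 to 32.2% on chromosome 11 among the autosomes, with 17.9% on X.

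Within the 8999 co-occupied sites the peaks of both factors were centred close together. The median distance between the centres of the Shox2 peak and the nearest overlapping Pbx peak was 142 bp (quartiles 63 and 289 bp). The Shox2 centre fell in the central 50% of the Pbx peak at 7076 sites (78.6%), against 38.5% of the 12324 pairs that 20 circular shifts produced. The deposited co-occupancy list held exactly these sites: all 8999 listed regions had the start and end of a Shox2 limb peak, stood in the order of the Shox2 list, and were the 8999 found here by 1 bp of overlap. It is therefore a subset of the Shox2 limb list and no independent measurement.

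**Figure D2:**
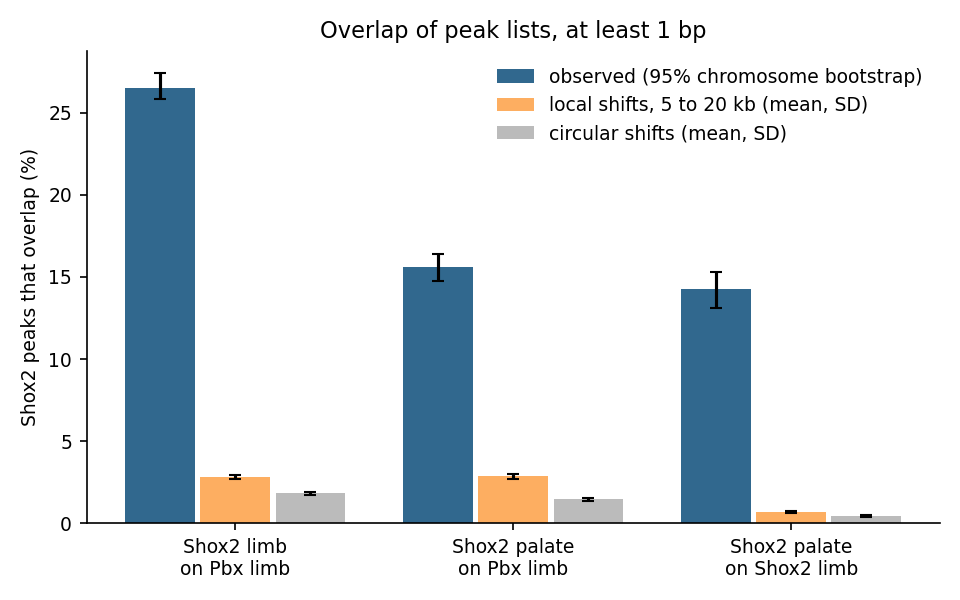
Share of Shox2 peaks (percent, linear axis from 0) that overlap the second list by at least 1 bp, with 95% chromosome bootstrap intervals, beside the mean and SD over 1000 local shifts and 1000 circular shifts. The observed shares of 26.5%, 15.6% and 14.2% all lie above both chance levels.

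Co-occupancy was most frequent at the top of the Shox2 limb list. In the first decile of the list in file order, 55.9% of Shox2 limb peaks overlapped Pbx, and in the ninth and last deciles 15.5% and 18.0% did. Peaks also narrow down the list, from a median of 514 bp to 205 bp. With every peak set to 200 bp the shares were 39.8% (interval 38.1 to 41.3%) in the first decile and 9.23% (8.18 to 10.4%) in the last. In the Pbx list, at 200 bp, 27.2% of the first decile and 9.61% of the last overlapped a Shox2 limb peak (43.1% and 12.9% at the deposited extents).

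**Figure D3:**
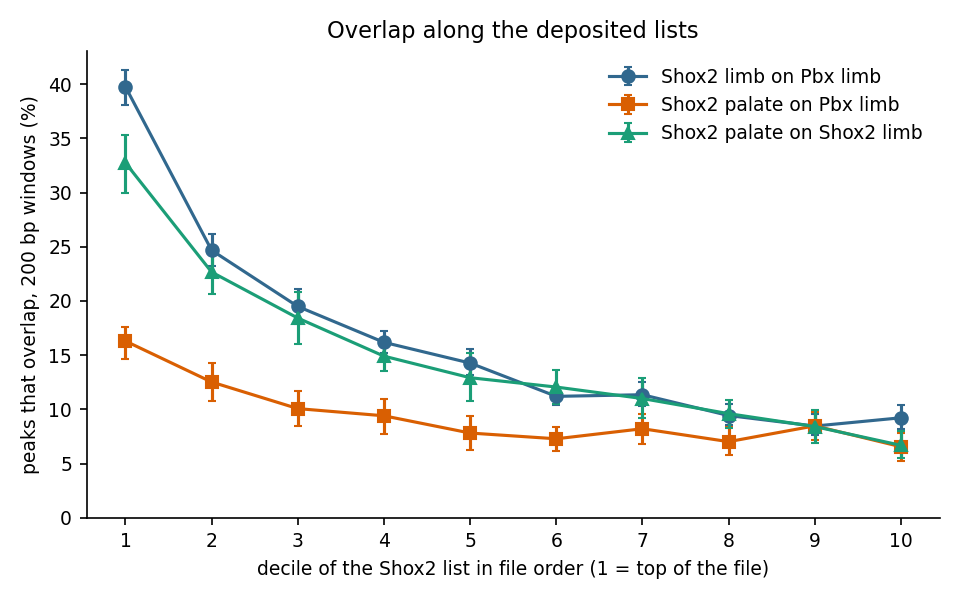
Share of Shox2 peaks (percent, linear axis from 0) that overlap Pbx limb or Shox2 limb peaks in each decile of the Shox2 limb or palate list in file order, with every peak set to 200 bp and 95% chromosome bootstrap intervals. Limb Shox2 on Pbx falls from 39.8% to 9.23%, palate Shox2 on limb Shox2 from 32.7% to 6.69%, and palate Shox2 on Pbx from 16.3% to 6.56%.

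Co-occupied sites were unevenly spread over the genome, as was the whole Shox2 limb list, with a median of 11 and at most 93 peaks per 1 Mb window. Whether co-occupied sites cluster more than Shox2 limb peaks do was not tested. Over the 2504 windows of 1 Mb that held any peak, the median was 2 co-occupied sites, and 549 windows had none. The densest were chromosome 3 from 66 to 67 Mb and chromosome 14 from 23 to 24 Mb, with 35 co-occupied sites each. The window on chromosome 3 also held the most Shox2 limb peaks in the genome, 93, together with 33 Pbx peaks and 19 palate Shox2 peaks. The window on chromosome 14 held 73 Shox2 limb peaks and 46 Pbx peaks. Chromosome 9 from 87 to 88 Mb had 34 co-occupied sites, chromosome 1 from 165 to 166 Mb had 33, and chromosome 18 from 55 to 56 Mb had 32. These 5 windows were also the 5 with the most Shox2 limb peaks overall.

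Co-occupied sites made up 37.6 to 48.6% of the Shox2 limb peaks in these 5 windows. The other windows among the densest 10 had fewer Shox2 limb peaks, and in most of them a larger share was co-occupied. All were picked by their count of co-occupied sites, so a larger share goes with fewer Shox2 peaks by construction. They held 27 (chromosome 15) to 58 (chromosome 12) Pbx peaks, against 28 to 46 in the first 5. No chance level was computed for single windows. On chromosome 8 from 27 to 28 Mb, 26 of 32 Shox2 limb peaks (81.3%) lay on Pbx. On chromosome 7 from 143 to 144 Mb, 30 of 48 did (62.5%), and on chromosome 12 from 74 to 75 Mb, 29 of 48 (60.4%). Chromosome 15 from 50 to 51 Mb had 29 co-occupied sites among 53 Shox2 limb peaks (54.7%), and chromosome 13 from 32 to 33 Mb had 29 among 61 (47.5%). The genes in these windows were not identified, since no mm9 annotation was used here.

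The second comparison set Shox2 binding in the palate against that in the limb at the same stage. Of the palate Shox2 positions, 2150 (14.2%, interval 13.1 to 15.3%) lay inside a Shox2 limb peak, against 0.436% by circular shifts, a 32.7-fold excess, and 0.674% by local shifts, a 21.1-fold excess (permutation test, one-sided p = 0.001 for both, the smallest possible). They fell in 2129 Shox2 limb peaks, 6.28% of that list. Most sites of either list were thus found in 1 tissue alone, although a site missing from a list was not shown to be unbound. The shared sites stood high in the palate list: 32.4% of its first decile and 5.89% of its last decile lay in a limb peak.

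The limb and palate Shox2 lists were spread differently over the genome. Each tissue had 1 library and the cutoffs of the lists are unknown, so a difference between libraries cannot be told from one between tissues. Among 2259 windows of 1 Mb with at least 5 Shox2 peaks, 118 held a larger share of the limb list and 243 a larger share of the palate list (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p under the threshold of 0.05). Of the 118 windows toward limb, 43 held 0 palate peaks. The smallest p toward limb was on chromosome 10 from 103 to 104 Mb, with 45 limb peaks and 1 palate peak (exact test, adjusted p = 0.000105). It was followed by chromosome 13 from 32 to 33 Mb, with 61 limb and 4 palate peaks (exact test, adjusted p = 0.00014), which was also among the windows densest in co-occupied sites. Chromosome 9 from 84 to 85 Mb had 53 limb and 3 palate peaks, chromosome 12 from 93 to 94 Mb had 40 and 1, and chromosome 13 from 26 to 27 Mb had 51 and 3.

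Toward palate, the smallest p was on chromosome 5 from 115 to 116 Mb, with 23 palate peaks and 1 limb peak (exact test, adjusted p = 6.47e-08). Chromosome 2 from 172 to 173 Mb had 29 palate and 6 limb peaks, chromosome 5 from 38 to 39 Mb had 31 and 8, chromosome 17 from 29 to 30 Mb had 17 and 0, and chromosome 2 from 166 to 167 Mb had 20 and 2. Windows toward palate were rich in limb Pbx peaks, with a median of 25 per window, against 10 in windows toward limb and 12 in all windows tested. The palate Shox2 peaks themselves lay on Pbx at similar rates: 17.4% in windows toward palate, 16.2% in windows toward limb and 15.6% in the whole palate list. Peaks cluster within windows, so these p-values are too small. The counts also moved with the window size and the list length: windows of 500 kb gave 34 toward limb and 184 toward palate, and at 1 Mb the limb list gave 61 and 129 when thinned at random to 15091 peaks and 72 and 134 when cut to its first 15091.

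**Figure D4:**
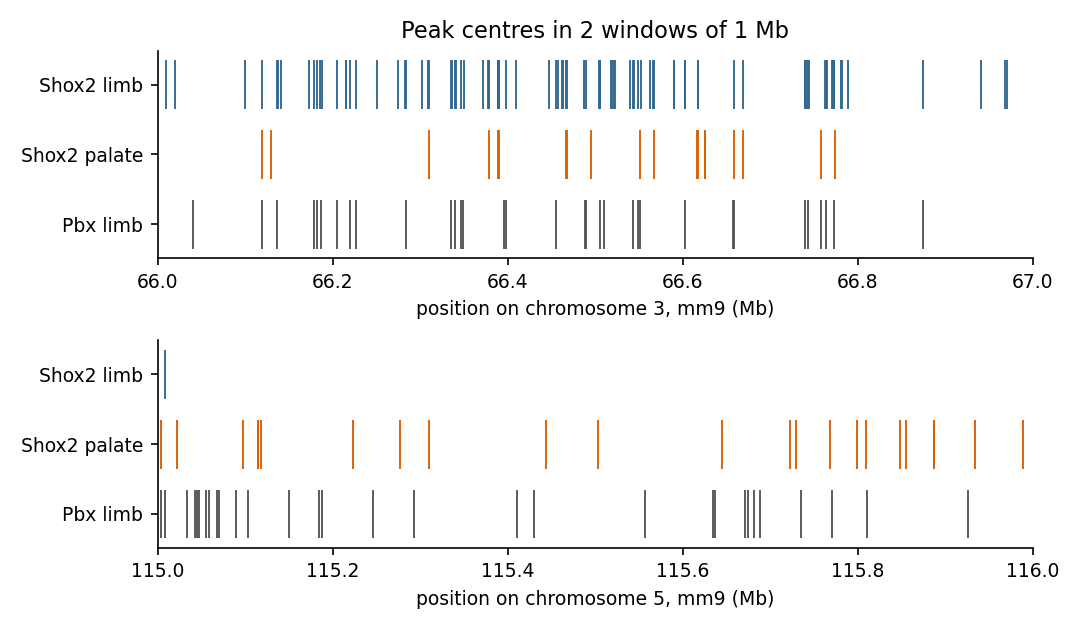
Centres of Shox2 limb, Shox2 palate and Pbx limb peaks (1 line per peak, position in Mb of mm9) in the window densest in co-occupied sites, on chromosome 3, and in the window with the smallest p toward palate, on chromosome 5. The first holds 93 Shox2 limb peaks and 19 palate peaks, and the second 1 and 23.

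Pbx was profiled in the limb only, and its sites there were compared with Shox2 sites of both tissues. Of the palate Shox2 positions, 2354 (15.6%, interval 14.7 to 16.4%) lay in a Pbx limb peak, against 1.45% by circular shifts, a 10.7-fold excess, and 2.85% by local shifts, a 5.48-fold excess (permutation test, one-sided p = 0.001 for both). With every peak set to 200 bp, so that limb and palate lists had the same extent, 16.4% of limb and 9.37% of palate Shox2 peaks overlapped Pbx. The difference was 7.04 percentage points (interval 6.61 to 7.50; two-sided Fisher's exact p = 2.71e-100). The lists differ in length and overlap falls down each of them: with the limb list cut to its first 15091 peaks, 23.9% of limb against 9.37% of palate peaks overlapped Pbx. Keeping the top of the limb list had to widen the gap, so this cut does not settle the part played by list length. By decile, limb and palate shares were 39.8% and 16.3% in the first, 8.46% and 8.48% in the ninth, and 9.23% and 6.56% in the last. The 12941 palate positions outside every Shox2 limb peak still lay on Pbx limb peaks in 1572 cases (12.1%), above the 1.46% by circular shifts and the 2.84% by local shifts (permutation p = 0.001 for both).

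Shox2 sites found in both tissues lay on Pbx more often than sites found in limb alone. Of the 2129 limb peaks that held a palate position, 781 (36.7%) overlapped Pbx, and of the 31786 limb-only peaks 8218 (25.9%) did. The difference was 10.8 percentage points (interval 8.91 to 13.1; odds ratio 1.66, two-sided Fisher's exact p = 2.38e-26). Among palate positions the gap was wider, with 36.4% of the 2150 shared and 12.1% of the 12941 palate-only positions on Pbx, a difference of 24.2 percentage points (interval 22.3 to 26.1). This gap was not adjusted for place in the palate list, down which both overlaps fall, and shared positions lie by definition in limb peaks, 26.5% of which are on Pbx. Shared limb peaks also stood higher in the limb list, 69.2% of them in its first 50% against 48.7% of limb-only peaks, and were wider, with medians of 333 and 257 bp. Within deciles of the list and of width together, with only the Pbx overlap taken at 200 bp, the odds ratio for shared against limb-only peaks was 1.14. Its interval over chromosomes was 0.996 to 1.30, which includes 1. The Cochran-Mantel-Haenszel chi-square test, which treats peaks as independent, gave p = 0.0197. In all, 781 limb Shox2 peaks (2.30%) were shared with both the palate and Pbx lists, and 23568 (69.5%) with neither.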

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

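Shox2 peaks of limb and palate differed in their overlap with Pbx limb peaks, by 7.04 percentage points (interval 6.61 to 7.50) with every peak set to 200 bp. The limb list is the longer one, and its first 15091 peaks gave 23.9% against 9.37% in palate. Overlap falls down the limb list, so this cut had to widen the gap. Equal numbers of peaks need not mean equal cutoffs, so the part played by list length was not settled. Limb and palate shares were 39.8% and 16.3% in the first deciles of the lists. They were 8.46% and 8.48% in the ninth and 9.23% and 6.56% in the last. Other technical explanations were not tested.

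The X chromosome held 2.08% of limb and 0.848% of palate Shox2 peaks, an odds ratio of 2.48 (95% exact interval 2.05 to 3.02, Fisher's exact p = 4.85e-25). The limb lists of Shox2 and Pbx, of equal length, differed too, with an odds ratio of 1.83 (interval 1.61 to 2.08) for Shox2 over Pbx, so unequal X shares were not confined to the contrast of tissues. Unequal shares of limb and palate Shox2 peaks were not confined to X either. Chromosome 3 held 8.13% of limb and 5.84% of palate peaks, and chromosome 11 held 3.84% and 5.93%. Single autosomes were not tested, so the small p is not shown to be particular to X. Cutting the limb Shox2 list to its first 15091 peaks lowered the odds ratio to 2.24 (interval 1.81 to 2.79). A gap to palate thus remained at equal numbers of peaks. File order is only a possible ranking, and equal numbers need not mean equal cutoffs. The part played by list length was therefore not settled. Without the 5 X windows with the most limb peaks, the ratio was 2.20 (interval 1.80 to 2.71). This argues against a few crowded loci. These intervals treat peaks as independent and are too narrow. A difference between libraries in the mix of male and female embryos, or in enrichment, and a biological difference between the tissues all stay open and were not tested.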

How the results depend on the processing

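All 9 alternatives kept the overlap of limb Shox2 with Pbx above chance (5.31 to 26.7%, 9.44-fold to 38.7-fold over shifted peaks), as did all 8 for palate Shox2 on Pbx (5.62 to 15.6%, 5.48-fold to 20.02-fold) and all 8 for palate on limb Shox2 (6.25 to 14.9%, 21.1-fold to 50.7-fold). The excess of Pbx overlap at tissue-shared over limb-only peaks ranged from 3.35 to 10.8 percentage points over 7 alternatives and stayed past the threshold of Fisher's exact test in each; holding list place and width fixed together was a separate test. Of these, the first 50% of each list in file order was chosen after the data were seen. An overlap of 50% of both peaks could not be required for palate positions of 1 bp, which also have no widest 50%, so the whole palate list was kept there. None of the listed co-occupied regions (0%) was identical to a Pbx peak, and 87.5% were identical to the stretch shared by both peaks, which holds where the Shox2 peak lies wholly within the Pbx peak. Of the windows between limb and palate, 118 and 243 as reported, thinning the limb list left 61 toward limb and 129 toward palate, of which 53 and 121 were among those reported. Taking the first limb peaks in file order left 72 and 134, and windows of 500 kb gave 34 and 184 (both chosen after seeing the data). Fewer peaks per test lower the counts in these by construction. The planned rule of at least 10 peaks per window gave 122 toward limb and 207 toward palate. Of those, 118 and 201 were among the windows reported. The 10 named windows were retested with the thinned list, with the first limb peaks and with at least 10 peaks per window, and in these only chromosome 13 from 26 to 27 Mb lost its call, with the thinned list (exact test, adjusted p = 0.0639). The rule of at least 10 peaks left the counts of these windows unchanged, so it could not take a call away. The thinned and cut lists are parts of the list that picked the windows, so these retests are no independent support. In windows of 500 kb the densest 10 held 38.2 co-occupied sites per Mb, against 31.2, and 6 of them lay in the 10 windows named. Alternatives for promoters, gene lists, distances to genes and motifs were not run, for want of an mm9 annotation. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Depth is unknown, so a site missing from a list cannot be told from one below the cutoff of that list.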

Other observations

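Windows in which the palate list was denser than the limb list stood apart in their Pbx peaks. The 243 windows toward palate held 6627 limb Pbx peaks, a mean of 27.3 per window, and the 118 toward limb held 1477. In windows toward palate, 37.8% of the 1242 limb Shox2 peaks lay on Pbx, against 27.3% of the 3680 in windows toward limb. Of the palate Shox2 peaks, 17.4% lay on Pbx in windows toward palate and 16.2% in windows toward limb. No chance level was computed for these shares, and windows with more Pbx peaks give more overlap by chance. On X, 126 of 705 limb Shox2 peaks (17.9%) lay on Pbx, against 26.7% on the autosomes (two-sided Fisher's exact p = 5.05e-08). This lower share goes with far fewer Pbx peaks on X, 2.42 per Mb against 11.6 to 18.3 on the autosomes, and was not set against a chance level for X. Of the 128 palate Shox2 peaks on X, 13.3% lay on Pbx, which is within the autosomal range of 12.8 to 19.3%. No interval was computed for so few peaks, so a lower share on X like that in limb is neither shown nor excluded in palate.

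Tissue-shared limb sites lay on Pbx more often than limb-only sites, with an odds ratio of 1.66 at the deposited extents and 1.64 at 200 bp. Shared sites also stood higher in the list. For the odds ratios at 200 bp, only the Pbx overlap was set to that width. Sharing was judged at the deposited extents, where a wider limb peak holds a palate position more easily. With every peak at 200 bp, also for sharing, 22.6% of shared and 16.0% of limb-only peaks lay on Pbx. The joint test of list place and width was chosen after the separate tests were seen. Within deciles of the list the odds ratio fell to 1.25 (interval 1.13 to 1.40) at the deposited extents and 1.19 (interval 1.05 to 1.37) at 200 bp. Within deciles of width it was 1.26 (interval 1.10 to 1.43) at 200 bp. These ratios stayed above 1, but peaks still differ in place and width within a decile. Neither test can therefore exclude place or width as the source of the excess. Place and width held fixed together at 200 bp left 1.14 (interval 0.996 to 1.30). The Cochran-Mantel-Haenszel chi-square test, which treats peaks as independent, gave p = 0.0197. The interval and the test thus point different ways. Much of the excess may go with strong sites being found by either antibody and in both tissues, if file order and width stand for strength, and whether that is all of it stays open, beside a biological link between tissue sharing and Pbx.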
